A study of Mus musculus with 12 samples.

How the data were processed

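RNA was measured in 12 libraries from the cortex and hippocampal formation of 6 mouse embryos at E17.5, with a rostral and a caudal library titled for each. Per the labels' protocols, messenger RNA was captured from total RNA and sequenced as paired reads. Per the submitters' processing notes, reads were aligned with STAR 2.7.8a to GRCm39 and counted with featureCounts 2.0.3, and per the file headers the annotation was GENCODE release 28 for mouse (vM28), fragments were counted on the reverse strand, and reads that map to several places or overlap several genes were counted in fractions. The deposited values are therefore estimated counts per gene (expected counts), of which the authors' files list 55357 genes, with no normalization. Between 21.6% and 23.9% of the genes detected in a library had a value that is not whole. Fractional counting spreads reads of near-identical copies over all of them, so counts of pseudogenes and their parents are uncertain. Reference annotation of another build was not used for coordinates, which are those of the files.

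Counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr, robust quasi-likelihood fits and a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size over the square root of the test's F. Levels are CPM (counts scaled to a total of 1e+06) computed from the deposited counts; the Egfr means are scaled by TMM, the per-library levels of Gh, Xist, Y genes and Nr2f1 by the library size, and other means by TMM within their comparison. Knockout was compared with control in the 6 libraries of each part and in the sums of both parts per titled embryo (3 against 3, 4 residual degrees of freedom). Caudal was compared with rostral within embryos, and the interaction tested, in 1 model of the 12 libraries with the embryo as a block (4 residual degrees of freedom). The samples' groups, tests, alternatives and lists were fixed before the data were examined. Groups came from the labels, and no library was moved to another group or left out of the main tests. The litters or dams behind the numbers 4858 and 4692 in the titles, and whether controls carry Cre, are not given in the sources used here.

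In all, 41 gene lists were fixed, and in each comparison those with at least 3 tested members were tested with limma 3.58.1, by camera with a preset correlation of 0.01 on log2 CPM (prior count 2), by camera with an estimated correlation and by fry. Genes named are Egfr, up to 10 genes per direction with the largest change among those called at a mean of at least 1 CPM with groups that do not overlap in the libraries or sums tested, the 10 with the smallest p where fewer than 10 were called, and up to 4 called members of each list, or the 2 with the smallest p. Predicted genes, pseudogenes and sex-linked genes are left out by that rule; 2610507I01Rik, the Rpl30-like copies and Nr2f1 were named after their values were seen, as was Gh in the pituitary comparison. Not every gene the rule allows is printed.

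The alternatives tried were DESeq2's size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter, each embryo left out, X and Y genes left out, glmTreat against a fold change of 1.2, the number before the embryo number as a block, all 12 libraries in 1 fit, and limma-voom with the embryo as a random effect. Fits with 2 surrogate variables (sva 3.50.0), with Xist as a covariate, with all 12 libraries as separate samples, and without 2 control libraries that held transcripts of both sexes were added after the data were seen. The 2 surrogate variables were settled on after fits with 0 to 4 had been looked at.

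The titles give both parts of an embryo the same number. The pairing was checked by correlating, over 1000 autosomal genes, each library's deviation from its group mean with that of its partner. The 6 correlations were -0.374, -0.59 and -0.378 in knockout embryos 5, 2 and 7, and -0.148, -0.632 and -0.494 in control embryos 1, 3 and 9, so that 0 of 6 exceeded 0.1 and all 6 were negative. The 12 correlations with libraries of other embryos ran from -0.205 to 0.626, with 9 above 0.1, and the own correlation was the lowest of 3 in 5 of 6 embryos. Centring on group means ties the 3 correlations of a library to one another, but not which of them is lowest. The titled pairing is thus not borne out by these values, and sums and blocks by titled embryo rest on the titles alone. Replicates of a group differed by far more than sampling noise, and none was a copy of another.

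The tests were checked on simulated counts with 200 changed genes, drawn only from genes above a floor of mean count. In the summed comparison (18683 genes), 70.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 20 unchanged genes. In caudal libraries (16721 genes) the shares were 20.9%, 80.6% and 98.5%, with 10 unchanged genes. In rostral libraries (16873 genes) they were 2.99%, 52.2% and 92.4%, with 8 unchanged genes, and for caudal against rostral in controls (17517 genes) 4.48%, 58.2% and 83.3%, with 12. The simulated libraries and sums were independent, with the spread found between the titled ones. The shares therefore do not hold for separate embryos, whose spread is not known here. With lists simulated in the summed comparison (18937 genes), camera called the changed list in 10 of 10 simulations and 0 of 390 unchanged lists. The simulated genes were independent of one another, so this gives no error rate for real lists, whose estimated correlations reached 0.915 in that comparison. Figures were drawn with matplotlib 3.10.9.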

Results

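Messenger RNA was sequenced from the cerebral cortex, dissected with the hippocampal formation, of E17.5 mouse embryos. Knockout embryos carried a Nestin-Cre transgene, which drives Cre recombinase in neural progenitors, and 2 floxed alleles of Egfr, the gene of the epidermal growth factor receptor. Control embryos carried 1 floxed and 1 intact allele. Each dissected cortex was divided into a rostral and a caudal part. The titles assign 12 libraries from 6 embryos to 4 groups of 3, knockout rostral, knockout caudal, control rostral and control caudal. Total counts per library ran from 25223733 to 30383672, and between 25682 and 27178 genes had a count above 0. Mitochondrial genes took 7.25% of the counts in knockout rostral replicate 7 and 4.77% in knockout caudal replicate 5, and between 1.96% and 3.53% in the other libraries. Chosen after results were seen were the comparisons of libraries by sex-linked and on-or-off transcripts and the fit of all 12 libraries as separate samples.

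The knocked-out gene separated the genotypes in every library. Egfr (ENSMUSG00000020122.17, GRCm39 chromosome 11, 16702203 to 16868158) stood at 5.17 ± 1.78 CPM (SD, n = 3) in knockout and 24.9 ± 6.34 CPM (SD, n = 3) in control libraries labelled rostral, that is at 20.7% of control. In libraries labelled caudal it stood at 6.52 ± 0.867 CPM against 36.3 ± 6.27 CPM (SD, n = 3 each), 17.96% of control. The exact two-sided permutation p was 0.1 in each part, the smallest that 3 against 3 can give. Growth hormone, Gh (ENSMUSG00000020713.7, chromosome 11, 106191097 to 106192691), gave 165.5 to 235.5 counts in each of the 6 knockout libraries and 0 counts in the 6 control libraries. Its mean of 7.11 ± 0.830 CPM (SD, n = 6) was at least 373-fold higher than the floor of 0.0191 CPM that 3 counts over the 157313294 counts of the control libraries together allow. This floor covers counting error only.

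**Figure D1:**
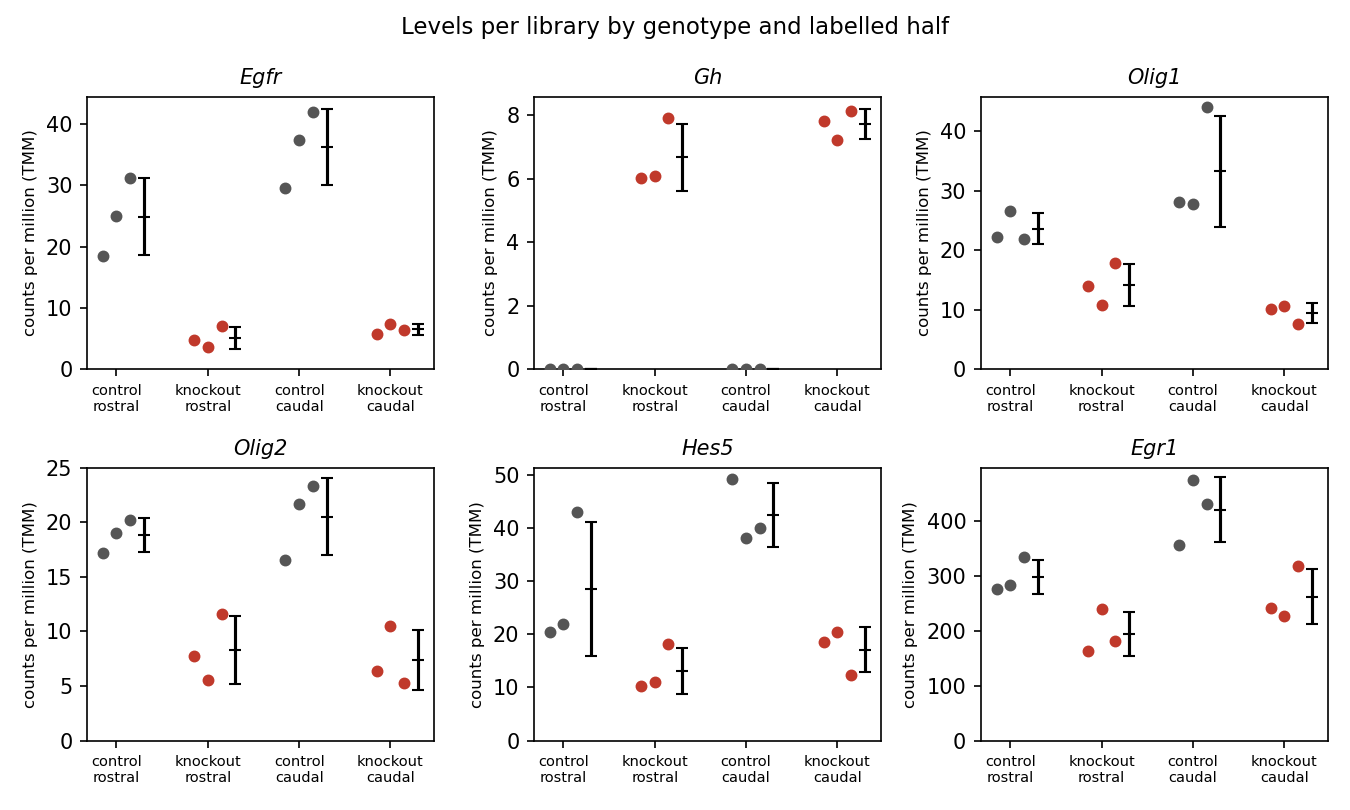
CPM, scaled by TMM, of 6 genes in each of the 12 libraries (points), with the mean and SD of each group of 3 (bar and whiskers), by genotype and labelled part. Egfr in knockout libraries lay at 20.7% (rostral) and 17.96% (caudal) of control, and Gh was found in knockout libraries alone.

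Other transcripts did not follow the titles. Xist, expressed from the inactive X chromosome of females, and 4 genes of the Y chromosome (Ddx3y, Kdm5d, Eif2s3y and Uty) should be alike in the rostral and caudal parts of 1 embryo. They were alike in 1 of the 6 embryos, knockout embryo 7, where Xist was at 450 and 376 CPM. Knockout embryos 5 and 2 and control embryo 9 held Y transcripts without Xist in the library labelled rostral (152, 162 and 172 CPM) and Xist with hardly any Y transcripts in the one labelled caudal (324, 426 and 253 CPM). Control libraries labelled rostral 1 and 3 held both, with Xist at 230 and 278 CPM and Y transcripts at 94.6 and 92.0 CPM. Their caudal partners held Y transcripts (178 CPM) and Xist (488 CPM), respectively. Nr2f1, a transcription factor known to be higher in caudal than in rostral cortex, was at 78.9, 348 and 50.7 CPM in control libraries labelled rostral 1, 3 and 9 and at 343, 58.6 and 373 CPM in those labelled caudal 1, 3 and 9. In knockout libraries labelled 5, 2 and 7 it was at 97.1, 340 and 205 CPM (rostral) and at 248, 71.3 and 348 CPM (caudal).

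Over 8 features, the sex class and 7 autosomal transcripts that were on or off in each library, every library matched 1 other library of its genotype completely, and in 0 of 12 cases this was its titled partner. The features are not separate evidence. Gm11222 was on only in the libraries with Xist alone, and Gm13727 and AA388235 were on in the same libraries. Gm46313 was on only where Gm35082 was off. Matching libraries were neighbours in accession order. Their Nr2f1 levels lay from 3.5-fold to 6.77-fold apart in 5 of the 6 matching pairs, and 1.21-fold apart in knockout rostral 7 and caudal 5. The 2 knockout libraries with Y transcripts alone were both labelled rostral, as were the 2 control libraries with both kinds, and the 2 control libraries with Xist alone were both labelled caudal. If each embryo gave 2 libraries, as titled, then by sex class alone 2 of the 3 libraries in each of these 3 groups come from 1 embryo. In knockout caudal libraries, all with Xist, the same holds for 2 and 7 if the autosomal transcripts do not differ between parts of 1 embryo. The n = 3 given below therefore counts libraries or titled sums and not embryos, and p-values measure the spread between these. The labels were kept in all tests, so every statement on a part or an embryo concerns libraries as labelled, and no test was run on libraries grouped by these transcripts. A fit that leaves out 1 embryo drops the libraries of 1 titled embryo. In the summed and 12-library comparisons, the libraries that match those dropped stay in. If matching libraries come from 1 embryo, such a fit leaves out no embryo in full. A call that stays then shows no stability over embryos.

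**Figure D2:**
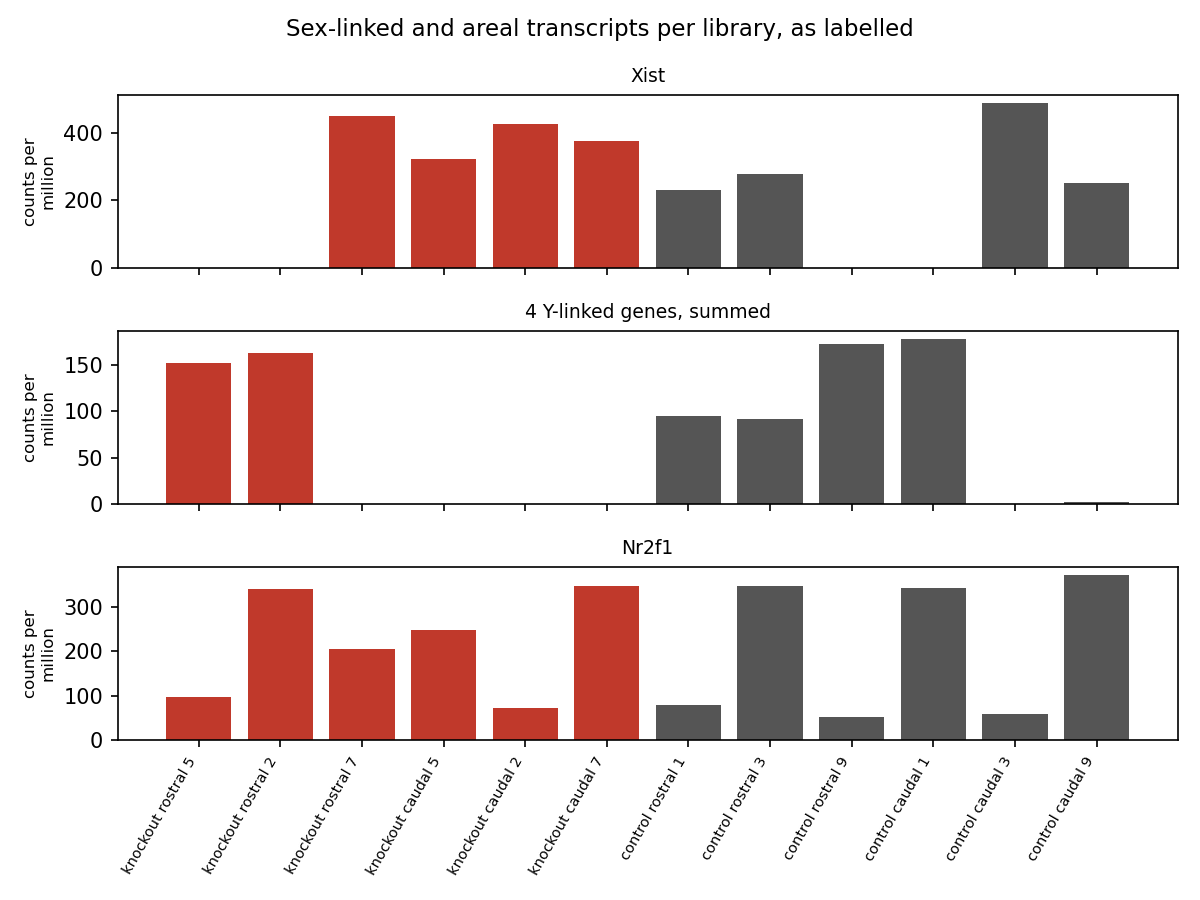
CPM of Xist, of 4 Y-linked genes summed, and of Nr2f1 in each library, named as in the titles (knockout red, control grey). Of the 6 labelled pairs of rostral and caudal libraries, 1 agrees in its sex-linked transcripts, and 2 control libraries labelled rostral hold both kinds.

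To ask what differed between knockout and control over the whole cortex, the counts of the libraries titled rostral and caudal of 1 embryo were summed. The titles name Cre in knockout libraries alone, and whether controls carry it is not given. For every gene and list below, an effect of Egfr loss therefore cannot be told apart from an effect of the Cre transgene. Transcripts of 3 transcription factors of glial progenitors were called lower together with Egfr. Olig2 and Olig1, which specify oligodendrocyte precursors, were at 7.83 ± 0.768 against 19.7 ± 2.46 CPM and at 11.88 ± 1.2 against 28.4 ± 3.93 CPM (knockout against control, SD, n = 3 each). Hes5, a Notch effector of radial glia and glial progenitors, was at 15.2 ± 0.415 against 35.5 ± 5.73 CPM. Their log2 fold changes were -1.33 (SE 0.12, adjusted p = 0.00752), -1.26 (SE 0.12, adjusted p = 0.0084) and -1.23 (SE 0.11, adjusted p = 0.0084) by edgeR's quasi-likelihood test, and Egfr's was -2.39 (SE 0.17, adjusted p = 0.00556). In the single libraries, whatever their pairing, Olig2 ran from 5.27 to 11.62 CPM in knockout and from 16.55 to 23.33 CPM in control, Olig1 from 7.64 to 17.87 and from 21.97 to 44.02 CPM, and Hes5 from 10.24 to 20.47 and from 20.48 to 49.39 CPM (n = 6 libraries each). Each sum joins 2 libraries that matched different partners, so the sums of a genotype are not separate embryos, and their SD, such as 0.415 CPM for Hes5, and p-values do not measure the spread between embryos. The common biological coefficient of variation was 0.111 for the sums, against 0.223 in rostral and 0.18 in caudal libraries. These 3 genes lie on GRCm39 chromosome 16 (Olig2 from 91022345 to 91025565 and Olig1 from 91066660 to 91068821) and chromosome 4 (Hes5, 155045380 to 155046828). The other 2 of the 6 genes called were higher, Gh and the non-coding 2610507I01Rik (chromosome 11, 59090662 to 59093211), whose log2 fold change was 2.89 (SE 0.18, adjusted p = 0.00112). In all, 6 of 18937 genes were called, 643 had an unadjusted p under 0.05 where 946.8 would by chance, and DESeq2 called 33. Without embryo 5 the count was 3, since Egfr, Olig1 and Hes5 then had an adjusted p of 0.0785, and without embryo 1 Hes5 had one of 0.0648. Without embryo 2 the count was 21, and without embryo 3 it was 10. With all 12 libraries as separate samples, a fit that counts both parts of an embryo as replicates, Hes5 (adjusted p = 0.404) and Olig1 (adjusted p = 0.118) were not called. Over 15 alternatives the adjusted p ran from 1.55e-43 to 0.404 for Hes5, from 4.89e-39 to 0.135 for Olig1 and from 1.77e-32 to 0.0498 for Olig2.

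Several genes whose titled sums did not overlap had a small p without passing. Klf6 had a log2 fold change of -0.44 (adjusted p = 0.0867), the kinase gene Plk2 of -0.51 (adjusted p = 0.109), Rundc3b of -0.59 (adjusted p = 0.109), the ERK phosphatase gene Dusp5 of -0.91 (adjusted p = 0.121) and Egr1 of -0.66 (adjusted p = 0.121), all by edgeR. Among those higher, Padi4 had a log2 fold change of 3.65 (adjusted p = 0.121) and the peptide transporter gene Slc15a2 of 0.79 (adjusted p = 0.142). In the single libraries the genotypes overlapped for each of these 7 genes, with Klf6 at up to 70.52 CPM in knockout and down to 66.09 CPM in control, Egr1 at up to 318.6 and down to 276 CPM, and Slc15a2 down to 21.79 CPM in knockout and up to 26.82 CPM in control. Padi4 was at 0 CPM in knockout caudal 2 and 7, which matched each other above, at 3.408 to 7.093 CPM in the other 4 knockout libraries and at up to 0.6857 CPM in control.

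Of 40 gene lists with at least 3 tested members, 14 were called in the summed comparison by camera with a preset correlation of 0.01, 3 higher and 11 lower. None was called with a correlation estimated per list, nor by fry's directional test. By fry's test for change in either direction 7 were called. Called in each of the 6 fits that left out 1 titled embryo were immediate early genes, MAPK feedback targets, and markers of oligodendrocyte precursors, ventral forebrain and striatum, and choroid plexus (highest adjusted p 0.0409). Each of these fits kept the libraries that matched those left out. The median of MAPK feedback targets was -0.084 without embryo 3. Immediate early genes, which respond within minutes to receptor signalling and neuronal activity, were lower as a list (median log2 fold change -0.50, camera adjusted p = 1.67e-10; adjusted p = 0.505 with an estimated correlation). All 14 members had a negative sign and 7 passed when adjusted over the list alone, against 0 over all genes. Egr1 was at 228 ± 21.0 against 359 ± 37.0 CPM and Egr3 at 10.1 ± 2.01 against 20.0 ± 4.19 CPM (SD, n = 3 each). Feedback targets of the MAPK cascade, which Egfr activates, were lower too (median -0.14, camera adjusted p = 7.85e-05; adjusted p = 0.505 with an estimated correlation). Of 16 members, 15 had a negative sign and 3 passed when adjusted over the list alone, none over all genes. Dusp5 was at 4.34 ± 0.357 against 8.13 ± 1.09 CPM and Spry4 at 6.02 ± 0.720 against 8 ± 0.493 CPM (SD, n = 3 each). In the single libraries the genotypes overlapped for Egr1, Egr3, Dusp5 and Spry4. Spry4 ran from 3.215 to 9.407 CPM in knockout and from 4.767 to 10.38 CPM in control.

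Of the glial lists, oligodendrocyte precursor markers were lower (median -0.24, camera adjusted p = 8.76e-08; adjusted p = 0.505 with an estimated correlation), with 11 of 13 members negative, 2 called over all genes (Olig1 and Olig2) and 3 when adjusted over the list alone. Gliogenic regulators (adjusted p = 0.00158; adjusted p = 0.808 with an estimated correlation) and the Notch pathway (adjusted p = 0.00891; adjusted p = 0.808 with an estimated correlation) were lower, with 3 called members of 18 (Olig1, Olig2 and Hes5) and 1 of 13 (Hes5) and a median of -0.06 in each list. Astrocyte markers were higher (median 0.14, camera adjusted p = 0.00784; adjusted p = 0.808 with an estimated correlation), with 13 of 19 members positive, 0 called over all genes and 1 when adjusted over the list alone. That member, Gfap, an intermediate filament of astrocytes, was at 9.14 ± 1.09 against 5.80 ± 0.764 CPM, and Aldoc was at 132 ± 14.1 against 110.5 ± 7.39 CPM (SD, n = 3 each). In the single libraries Gfap ran from 2.481 to 16.97 CPM in knockout and from 1.984 to 11.47 CPM in control, and Aldoc overlapped too. ErbB receptors and ligands were called lower (camera adjusted p = 0.0334; adjusted p = 0.808 with an estimated correlation), and Egfr was the 1 called member of 11. This list holds the targeted gene and was not tested without it, so its call is no separate evidence on the other members. With 1 embryo left out, the calls were lost for gliogenic regulators (without 9; adjusted p = 0.207), the Notch pathway (2 or 9; up to 0.264), astrocyte markers (2, 7 or 1; up to 0.325) and ErbB receptors and ligands (5, 2, 3 or 9; up to 0.346). The median of gliogenic regulators ran from -0.159 without embryo 1 to 0.00713 without embryo 9. That of the Notch pathway ran from -0.145 without embryo 7 to -0.0407 without embryo 9. That of astrocyte markers ran from 0.0661 without embryo 1 to 0.204 without embryo 9. The median of precursor markers, still called, was -0.146 without embryo 5 and -0.154 without embryo 9.

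Immature neuron markers were higher (median 0.08, 10 of 10 positive, camera adjusted p = 0.0102; adjusted p = 0.505 with an estimated correlation), with Sema3c at 439 ± 28.5 against 356 ± 37.4 CPM and Unc5d at 358 ± 32.0 against 302 ± 33.5 CPM (SD, n = 3 each). Markers of neuronal intermediate progenitors were higher (median 0.18, 8 of 10 positive, adjusted p = 0.0219; adjusted p = 0.825 with an estimated correlation). Deep layer neuron markers were lower (median -0.21, 11 of 13 negative, adjusted p = 0.0306; adjusted p = 0.808 with an estimated correlation), for example Fezf2 at 33.2 ± 1.63 against 39.2 ± 3.35 CPM (SD, n = 3 each). In the single libraries Fezf2 ran from 13.92 to 54.55 CPM in knockout and from 18.09 to 53.48 CPM in control. GABAergic interneuron markers were lower (median -0.23, 16 of 16 negative, adjusted p = 0.00595; adjusted p = 0.808 with an estimated correlation), with Nxph1 at 13.6 ± 3.82 against 19.2 ± 2.90 CPM (SD, n = 3 each). Sema3c, Unc5d and Nxph1 overlapped between genotypes in the single libraries as well. Not 1 member of these 4 lists passed over all genes or when adjusted over the list alone. With 1 embryo left out, the calls were lost for immature neurons (without 2 or 3, adjusted p up to 0.188), intermediate progenitors (5, 7 or 3, up to 0.696), deep layer neurons (5, 7, 3 or 9, up to 0.494) and interneurons (5, 7 or 3, up to 0.485). The interneuron median ran from -0.361 without embryo 1 to -0.0335 without embryo 3. The deep layer one ran from -0.4 without embryo 2 to -0.0589 without embryo 7. The intermediate progenitor one ran from 0.0518 without embryo 3 to 0.265 without embryo 9.

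Markers of tissue next to the cortex were lower in the same comparison as the precursor and interneuron lists. Ventral forebrain and striatal markers were lower, with a median of -0.75 and 13 of 13 members negative (camera adjusted p = 3.09e-05; adjusted p = 0.746 with an estimated correlation). Choroid plexus markers (median -0.69, 5 of 6 negative, adjusted p = 0.00251; adjusted p = 0.505 with an estimated correlation) and cortical hem markers (median -0.33, 8 of 9 negative, adjusted p = 0.0344; adjusted p = 0.825 with an estimated correlation) were lower as well. Of the 13 choroid plexus markers listed, only 6 were tested, and several were low or uneven. In the single libraries Ttr ran from 0 to 5.79 CPM in knockout and from 0.03743 to 47.54 CPM in control. Clic6 reached at most 0.8272 CPM in knockout and 2.59 CPM in control, and Aqp1 at most 0.6259 and 0.8137 CPM. Ebf1, of the striatal list, was at 21.6 ± 8.15 against 38.8 ± 12.4 CPM, and Rspo3, of the hem list, at 19.2 ± 2.96 against 23.8 ± 3.20 CPM (SD, n = 3 each), with no member of the 3 lists passing over all genes or over the list alone. In the single libraries Ebf1 ran from 4.451 to 60.32 CPM in knockout and from 11.05 to 86.35 CPM in control, and Rspo3 overlapped too. The hem list was not called without embryo 7, 3 or 9 (adjusted p up to 0.947). Its median ran from -0.637 without embryo 2 to -0.0495 without embryo 7. The striatal median was -0.316 without embryo 3 and -1.08 without embryo 1, and the choroid plexus median -1.17 without embryo 5 and -0.459 without embryo 3. Of the markers of blood vessels, which were not called as a list by camera with the preset correlation (adjusted p = 0.263) but were by fry's test for either direction (adjusted p = 0.00431), Slco1c1 passed when adjusted over the list alone, at 57.2 ± 3.65 against 45.1 ± 1.98 CPM (SD, n = 3 each). In the single libraries Slco1c1 reached down to 51.18 CPM in knockout and up to 56.58 CPM in control.

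**Figure D3:**
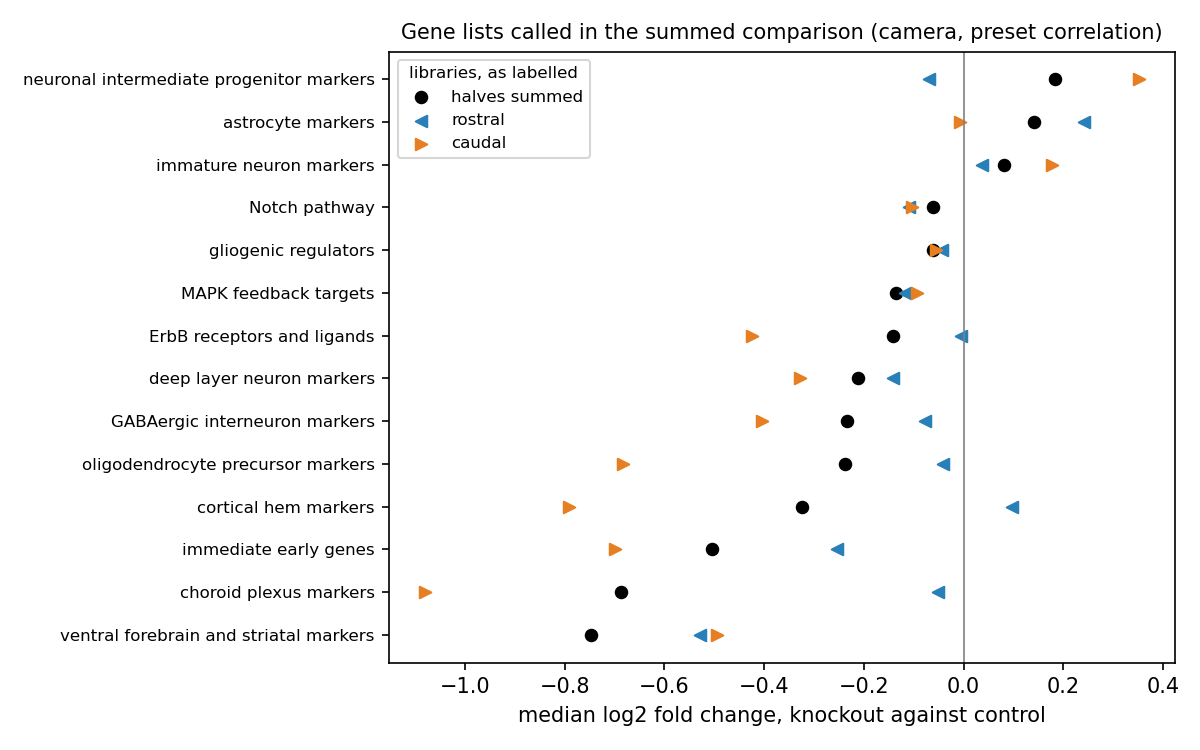
Median log2 fold change, knockout against control, of each of the 14 gene lists called by camera with a preset correlation in the summed comparison, for the embryo sums (circles) and for libraries labelled rostral and caudal (triangles). Ventral forebrain and striatal markers have a summed median of -0.75 (from -1.08 to -0.316 with 1 embryo left out), and none of the 14 lists is called with an estimated correlation.

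In libraries labelled caudal, knockout against control, 8 of 16964 genes were called by edgeR, 6 higher and 2 lower. Besides Egfr (log2 fold change -2.48, SE 0.17, adjusted p = 0.0025), Cdh13, a cadherin of neurons and vessels (chromosome 8, 119010472 to 120051660), was at 13.98 ± 1.25 against 31 ± 1.74 CPM (SD, n = 3 each) and was called lower (log2 fold change -1.15, SE 0.10, adjusted p = 0.0128). Of 15 alternatives, 9 did not call Cdh13, with log2 fold changes from -1.19 to -1.07 and adjusted p from 1.3e-13 to 0.999 over all 15. Its adjusted p was 0.0838 without embryo 5, 0.089 without embryo 7, 0.115 without embryo 1, 0.0594 without embryo 3 and 0.0743 without embryo 9. Gh rose, as did 5 copies resembling the ribosomal protein gene Rpl30, by log2 fold changes of 2.82 (Rpl30-ps10), 2.61 (Gm12191), 1.99 (Rpl30-ps1), 2.97 (Rpl30-ps9) and 2.82 (Gm7429). None of the 5 was called when all 12 libraries entered the fit (adjusted p from 0.794 to 1), and Gm7429 was not called in any of the 6 fits that left out 1 embryo (adjusted p from 0.0594 to 0.211). These copies can share reads with one another and with Rpl30, so their counts are uncertain. Control libraries labelled rostral 1 and 3 held them at 72.5 and 64.5 CPM summed, above the highest knockout library (60.1 CPM). Olig1 (log2 fold change -1.82, adjusted p = 0.0704), Hes5 (-1.32, adjusted p = 0.177) and Olig2 (-1.48, adjusted p = 0.353) had the sign of the summed comparison without passing. Plk2 (-0.72, adjusted p = 0.0621) and the Notch ligand gene Dner (-0.81, adjusted p = 0.0878) did not pass either. In all, 871 genes had an unadjusted p under 0.05 where 848.2 would by chance, and DESeq2 called 71. The count was 2 without embryo 5, where Egfr and Gh had an adjusted p of 0.0501, 4 without embryo 7 and 5 without embryo 9. Rpl30-ps1 and Rpl30-ps9 were not called without embryo 5 (adjusted p = 0.0688), 7 (0.0534) or 1 (0.0546), nor Rpl30-ps9 without embryo 9 (0.0606).

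By camera, 11 lists were called in libraries labelled caudal, 2 higher and 9 lower, and none with an estimated correlation or by fry's directional test. Oligodendrocyte precursor markers were lower in all 13 members (median -0.68, camera adjusted p = 3.41e-08; adjusted p = 0.737 with an estimated correlation), 4 of which passed when adjusted over the list alone and 0 over all genes. Immediate early genes were lower (median -0.70, 13 of 14 negative, 6 passing over the list alone and 0 over all genes, adjusted p = 3.41e-08; adjusted p = 0.737 with an estimated correlation), with Atf3 at 6.18 ± 0.406 against 11.3 ± 2.47 CPM and Egr3 at 11.2 ± 1.90 against 24.5 ± 8.58 CPM (SD, n = 3 each). GABAergic interneuron markers (median -0.41, adjusted p = 2.75e-06; adjusted p = 0.737 with an estimated correlation) and synaptic genes (median -0.51, adjusted p = 0.000288; adjusted p = 0.737 with an estimated correlation) were lower. Of their members 5 and 3 passed when adjusted over the list alone and 0 over all genes, with Nxph1 at 10.9 ± 2.35 against 20.9 ± 1.31 CPM and Gria1 at 73.9 ± 3.30 against 108 ± 14.3 CPM (SD, n = 3 each). Neuronal intermediate progenitor markers were higher (10 of 10 positive, median 0.35, 1 passing over the list alone, adjusted p = 0.000331; adjusted p = 0.737 with an estimated correlation), with Insm1 at 294 ± 34.3 against 220 ± 2.00 CPM (SD, n = 3 each). Proliferation genes were higher in 26 of 26 members (median 0.15, adjusted p = 0.0188; adjusted p = 0.777 with an estimated correlation). ErbB receptors and ligands were called lower (median -0.42, adjusted p = 0.00328; adjusted p = 0.737 with an estimated correlation), with Egfr, the targeted gene, their 1 called member. The list was not tested without Egfr here either. Gliogenic regulators (median -0.05, 3 passing over the list alone, adjusted p = 0.0217; adjusted p = 0.757 with an estimated correlation) and the Notch pathway (median -0.10, 1 passing over the list alone, adjusted p = 0.0488; adjusted p = 0.737 with an estimated correlation) were lower. Microglia markers (median -0.20, adjusted p = 0.00865; adjusted p = 0.757 with an estimated correlation) and endothelial markers (median -0.47, adjusted p = 0.00328; adjusted p = 0.757 with an estimated correlation) were lower in the same libraries, with no member passing. The list count was 19 without embryo 1 and 7 without embryo 9. Immediate early genes, synaptic genes and markers of oligodendrocyte precursors and interneurons stayed called whichever embryo was left out (adjusted p up to 0.0229). The interneuron median, however, was 0.0394 without embryo 3, -0.136 without embryo 7 and -0.89 without embryo 2, and the synaptic one was -0.266 without embryo 2 and -0.328 without embryo 9. Ventral forebrain and striatal markers were not called in these libraries (median -0.49, 11 of 12 negative, adjusted p = 0.0681). Control caudal 3 held Nkx2-1 (5.882 CPM), Penk (8.092 CPM) and Fgf15 (15.77 CPM) above the other 5 caudal libraries (at most 1.754, 2.247 and 3.218 CPM). Nkx2-1 and Penk are of the ventral list, and Fgf15 is of the list of rostral cortical patterning. Calls were lost for intermediate progenitors (without 3; adjusted p = 0.0576), ErbB (5; 0.11), proliferation (2 or 9; up to 0.528), gliogenic regulators (5 or 9; up to 0.373), endothelial markers (7 or 9; up to 0.263), microglia markers (2, 7 or 9; up to 0.263) and the Notch pathway (5, 7 or 9; up to 0.293). The sign of the median turned for proliferation genes without embryo 2 (-0.051) and for gliogenic regulators without embryo 5 (0.0318) or 9 (0.0263), and the ErbB median was -0.171 without embryo 3. The intermediate progenitor median ran from 0.157 (without 3) to 0.468 (9), and the Notch one from -0.174 (2) to -0.0212 (5). The endothelial median ran from -0.598 (2) to -0.216 (9), and the microglia one from -0.355 (5) to -0.0468 (9).

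In libraries labelled rostral, no gene was called by edgeR in the comparison of knockout with control. Of 17131 genes, 180 had an unadjusted p under 0.05 where 856.6 would by chance. DESeq2 called 4, edgeR on all 12 libraries in 1 fit called 2, and limma-voom on them called 1. Gh came nearest (adjusted p = 0.0897; adjusted p = 0.000474 with all 12 libraries in 1 fit). Egfr had a log2 fold change of -2.27 (SE 0.30, unadjusted p = 0.000146 by edgeR, adjusted p = 1; adjusted p = 0.0204 with all 12 libraries in 1 fit). Over 16 alternatives the adjusted p ran from 7.64e-12 to 1 for Gh, called in 4, and from 2.54e-10 to 1 for Egfr, called in 2. Olig2 (-1.19, SE 0.26), Olig1 (-0.74, SE 0.20), Hes5 (-1.12, SE 0.35) and Egr1 (-0.62, SE 0.16) carried the sign of the summed comparison. Camera called 8 lists, 3 higher and 5 lower, and none with an estimated correlation (adjusted p = 0.962 for each of the 8) or by fry's directional test. Immediate early genes (median -0.25, camera adjusted p = 9.56e-05), proliferation genes (median -0.24, 25 of 26 negative, adjusted p = 0.00166) and ventral forebrain and striatal markers (median -0.53, adjusted p = 0.0155) were lower, as were MAPK feedback targets (median -0.12, adjusted p = 0.0333) and gliogenic regulators (median -0.04, adjusted p = 0.0244). Astrocyte markers (median 0.24, adjusted p = 0.0122), microglia markers (median 0.52, 15 of 15 positive, adjusted p = 0.0122) and endothelial markers (median 0.27, adjusted p = 0.00374) were higher. The microglia genes Csf1r and C1qa were at 59.6 and 23.64 CPM in knockout rostral 7, the library with 7.25% mitochondrial counts, against 28.98 and 7.99 CPM in 5 and 23.68 and 7.545 CPM in 2. Without embryo 7 the microglia median was -0.0966 (adjusted p = 0.224) and the endothelial one 0.0601 (adjusted p = 0.366), so neither call held without that library. No list stayed called whichever embryo was left out. Besides those, calls were lost for immediate early genes (without 5; adjusted p = 0.112), proliferation (2 or 9; up to 0.93), astrocyte markers (7, 1 or 9; up to 0.413), gliogenic regulators (5, 7, 3 or 9; up to 0.458), MAPK feedback targets (2, 7, 1 or 9; up to 0.753) and striatal markers (5, 2, 1 or 9; up to 0.724). Microglia markers were not called without 1 or 3 either, nor endothelial markers without 5 or 9. The proliferation median was 0.0217 without embryo 9, and the striatal one -0.0803 without embryo 9 and -1.55 without embryo 7. That of immediate early genes was -0.146 without embryo 3 and ran from -0.46 without embryo 2 to -0.143 without embryo 5. The astrocyte median ran from 0.0998 without embryo 7 to 0.454 without embryo 3. The MAPK one ran from -0.254 without embryo 3 to -0.0427 without embryo 2. The list count was 5 without embryo 7, 5 without embryo 1 and 2 without embryo 9.

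The comparison of caudal with rostral libraries was meant to ask which genes differ along the cortex, which these labels cannot settle. In each genotype, a matching pair of libraries lay within the rostral group and another within the caudal group. Nr2f1 was low and high on each side. If matching libraries come from 1 embryo, differences between labels are mixed with differences between embryos, here and in the interaction. Within labelled embryos, edgeR called no gene in control embryos (353 with an unadjusted p under 0.05, 886.7 by chance, DESeq2 0) and no gene in knockout embryos (979 with an unadjusted p under 0.05, DESeq2 53). The control count was 3 without embryo 9. The block by titled embryo joins libraries that differ in sex class in 5 of 6 embryos, and without it the counts were 0 in both genotypes. Nr2f1 had a log2 difference of 1.17 (SE 1.34, adjusted p = 1) in control embryos, which was 2.52 without embryo 3, 0.19 without embryo 1 and -0.17 without embryo 9. The smallest p in control embryos belonged to Sh2d3c (log2 difference caudal minus rostral 0.73, SE 0.10, adjusted p = 1) and to the neuregulin receptor gene Erbb4 (0.59, SE 0.10, adjusted p = 1), at 139 ± 18.4 CPM in caudal and 92.9 ± 18.7 CPM in rostral libraries (SD, n = 3 each). In knockout embryos it belonged to the phosphatase gene Ptpn5 (-0.93, SE 0.10, adjusted p = 0.621) and to Dpp6 (-1.16, SE 0.17, adjusted p = 0.73), a subunit of potassium channels.

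Immediate early genes were higher in libraries labelled caudal in both genotypes by camera. Their median log2 difference was 0.55 in control embryos (14 of 14 positive, adjusted p = 3.8e-10; adjusted p = 0.419 with an estimated correlation) and 0.33 in knockout embryos (13 of 14 positive, adjusted p = 0.00131; adjusted p = 0.823 with an estimated correlation). Fosb was at 174 ± 17.6 CPM in caudal and 64.0 ± 32.3 CPM in rostral control libraries (SD, n = 3 each). In control embryos microglia markers were higher in caudal libraries too (median 0.71, 14 of 15 positive, adjusted p = 3.8e-10; adjusted p = 0.895 with an estimated correlation). Gliogenic regulators were higher as well (median 0.14, 17 of 18 positive, adjusted p = 0.0073; adjusted p = 0.419 with an estimated correlation). Markers of ependyma (median 0.57), border macrophages (median 1.60) and mural cells (median 0.35) were higher and cholesterol synthesis genes lower (median -0.10), each with an adjusted p of 0.0401 (adjusted p = 0.895 with an estimated correlation), which made 7 lists. In knockout embryos camera called 6 lists. Oligodendrocyte precursor markers (median -0.46, 12 of 13 negative, adjusted p = 0.000798; adjusted p = 0.823 with an estimated correlation) and synaptic genes (median -0.68, 14 of 14 negative, adjusted p = 8e-05; adjusted p = 0.823 with an estimated correlation) were lower in caudal libraries, as were endothelial markers (median -0.46, 12 of 12 negative, adjusted p = 0.00709; adjusted p = 0.842 with an estimated correlation). Neuronal intermediate progenitor markers (median 0.51, adjusted p = 3.9e-05; adjusted p = 0.823 with an estimated correlation) and proliferation genes (median 0.35, 26 of 26 positive, adjusted p = 0.000355; adjusted p = 0.874 with an estimated correlation) were higher. No list was called with an estimated correlation or by fry's directional test in either genotype. The count in control embryos was 12 without embryo 1 and 19 without embryo 3, and in knockout embryos 12 without embryo 2 and 10 without embryo 7. Called whichever embryo was left out were immediate early genes and microglia markers in controls and intermediate progenitor markers in knockouts. In controls, calls were lost for gliogenic regulators (without 9; adjusted p = 0.187), border macrophages (9; 0.37), ependyma (2 or 9; up to 0.0958), mural cells (5 or 9; up to 0.467) and cholesterol synthesis (3 or 9; up to 0.396). In knockouts, they were lost for immediate early genes (5; 0.202), oligodendrocyte precursors (7; 0.263), proliferation (2; 0.362), synaptic genes (2; 0.0667) and endothelial markers (5 or 7; up to 0.758). The proliferation median in knockouts was -0.0919 without embryo 2 and 0.702 without embryo 7. The synaptic median there ran from -1.05 without embryo 7 to -0.137 without embryo 2. The precursor one ran from -0.781 without embryo 2 to -0.238 without embryo 7, and the endothelial one from -0.803 to -0.0243 without the same embryos. That of immediate early genes ran from 0.161 without embryo 5 to 0.56 without embryo 2.

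Whether the effect of the knockout differed between the parts was tested as an interaction within labelled embryos, and edgeR called no gene (256 with an unadjusted p under 0.05, 886.7 by chance, DESeq2 0). The smallest p belonged to Erbb4, with a difference of -0.76 in log2 fold change (SE 0.14, adjusted p = 1). For Egfr the difference was -0.18 (SE 0.30, adjusted p = 1), and it was 0.086 without embryo 7 and -0.51 without embryo 2. Camera called 7 lists, 2 higher and 5 lower, and none with an estimated correlation or by fry's directional test. The list count was 14 without embryo 5, 16 without embryo 3, 4 without embryo 7 and 4 without embryo 9. Oligodendrocyte precursor and intermediate progenitor markers stayed called whichever embryo was left out (highest adjusted p 0.049 and 0.0497). Calls were lost for microglia (without 7; adjusted p = 0.835), endothelial (7 or 9; up to 0.489) and interneuron markers (7 or 3; up to 0.28), proliferation (2 or 9; up to 0.754) and synaptic genes (5, 2 or 9; up to 0.763). The sign of the median turned for interneuron markers, from -0.32 to 0.34 without embryo 7 and 0.154 without embryo 3, and for proliferation genes, from 0.35 to -0.112 without embryo 2. The intermediate progenitor median was 0.332 without embryo 5, against 0.52. Across the 16710 genes tested in both parts, the knockout's log2 fold changes in libraries labelled rostral and caudal had a Pearson r of 0.049 and a Spearman rho of -0.13, and 44.7% had the same sign. Of the 8 genes called in caudal libraries, 5 of them Rpl30-like copies that can share reads, 7 had the same sign in rostral ones. Genes are not independent replicates, and both sets of libraries are titled as coming from the same 6 embryos. With the labels of part in doubt, these values do not tell whether the knockout acts differently in the parts.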

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

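The weighing tests of this part were chosen after the results were seen, and the counts of other splits of the samples were planned. The effect of the knockout differed between libraries labelled rostral and caudal, by camera's test of the interaction with a preset correlation, for 7 lists. The mean difference in log2 fold change, caudal minus rostral, was -0.553 for oligodendrocyte precursor markers, 0.443 for neuronal intermediate progenitor markers, 0.352 for proliferation genes, -0.465 for GABAergic interneuron markers, -0.537 for microglia markers, -0.704 for endothelial markers and -0.564 for synaptic genes. None of the 7 was called with an estimated correlation (adjusted p from 0.679 to 0.951), and only the precursor and intermediate progenitor lists stayed called whichever embryo was left out. The median difference turned in sign for interneuron markers, to 0.34 without embryo 7 and 0.154 without embryo 3, and for proliferation genes, to -0.112 without embryo 2. The labels of part are themselves in doubt.

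The first pattern weighed is the disagreement of the titles' embryo and part with the sex-linked transcripts, for which no biological explanation was tested. Over 8 features (sex class and 7 autosomal transcripts that were above 1 CPM or below 0.1 CPM in every library), the 6 titled pairs agreed in 19 of 48 comparisons, and all 225 ways to pair the libraries within genotypes agreed at least as well. Several of the features repeat one another, so the 48 comparisons are not separate evidence. A mislabelled set of samples is a candidate explanation, since each of the 12 libraries had 1 library of its genotype that agreed at all 8 features, its neighbour in accession order and in 0 of 12 cases its titled other part. A mixed sample is argued against for the 3 embryos whose libraries each held 1 sex, where the other sex's transcripts reached at most 1.04% of the level in libraries of that sex. For the 2 control libraries labelled rostral with both kinds of transcript, Gm11222 cannot decide whether they hold RNA of a female embryo sequenced here. It was present in all 6 libraries with Xist alone and reached at most 0.0763 CPM in these 2. However, it is among the 7 transcripts kept for lying above 1 CPM or below 0.1 CPM in every library. A mixture at their lowest Xist share would need 0.674 CPM of it, a level that this choice leaves out. RNA of an embryo not sequenced here cannot be told apart from causes within these embryos, which were not tested. Y transcripts were at most 57.0% of the level in libraries with Y transcripts alone, and Xist lay inside the female range in 1 of the 2.

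The second pattern is the rise of 5 Rpl30-like copies in knockout libraries labelled caudal. A response to the loss of Egfr is argued against only by 2 control libraries, labelled rostral 1 and 3. They lay above the lowest knockout library in the 5 copies' summed CPM (72.5 and 64.5 against 43.0). These 2 libraries matched each other at all 8 features, so they may come from 1 embryo, and both held Xist and Y transcripts. The other 4 control libraries, at 6.97 to 9.30 CPM, lay under every knockout library. Reads shared between the copies remain a candidate explanation, since all 5 copies, on chromosomes X, 11 and 6, parted the 12 libraries at the same place. A strain variant carried by some embryos may supply the shared reads, with a gap of 4.63-fold between the lowest of 8 libraries and the highest of the other 4 (9.30 CPM). Rpl30 itself was at 160 and 162 CPM in control rostral 1 and 3. It was at 226 to 234 CPM in the control libraries low in the copies, and at 167 to 231 CPM in knockout libraries. Whether its reads were counted in the copies was not tested.

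The third pattern is Gh in all 6 knockout libraries and 0 of 6 control libraries. Pituitary tissue in the dissection is argued against, because among 8 pituitary markers fixed before that test the largest excess of the knockout mean was 0.0177 CPM, Cga was at 0 counts in every library, and Pomc was at 0.696 ± 0.0807 against 0.878 ± 0.143 CPM (SD, n = 6 each). A growth hormone sequence in the Cre transgene is a possible source that cannot be told apart from an effect of Egfr loss, with 0 libraries at odds with the genotype, since every knockout library carries both.

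Other splits of the same samples are too few for a share under 0.05 in any comparison. The counts of splits below include the real grouping itself. This holds also for the 4 splits by exchange, which change the labels of 1 embryo at a time. In libraries labelled rostral, 10 of 10 splits gave as many genes as the real one (0; highest other 20) and 7 of 10 as many lists (8; highest other 14). In libraries labelled caudal, 1 of 10 gave as many genes (8; highest other 3) and 4 of 10 as many lists (11; highest other 14). For the embryo sums, 2 of 10 gave as many genes (6; highest other 21) and 3 of 10 as many lists (14; highest other 15). For the interaction, 10 of 10 gave as many genes (0; highest other 25) and 8 of 10 as many lists (7; highest other 14). With caudal and rostral exchanged within embryos, all 4 splits gave as many genes in each genotype (0; highest other 0), 3 of 4 as many lists in controls (7; highest other 15) and 4 of 4 in knockouts (6; highest other 16). In the rostral, summed and interaction comparisons 1 split each called 20, 21 and 25 genes, against 0, 6 and 0 for the real one. The rostral split with 20 genes set knockout 5 and control 1 and 9 against knockout 2 and 7 and control 3. Nr2f1 was at 97.1, 78.9 and 50.7 CPM in the former and at 340, 205 and 348 CPM in the latter. The interaction split with 25 genes parted the titled embryos of these numbers in the same way. Whether Nr2f1 levels go with the genes called in these splits was not tested, nor what the summed split shares.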

How the results depend on the processing

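Fits with surrogate variables, with Xist as a covariate, with all 12 libraries as separate samples or without the 2 control libraries that held Xist and Y transcripts together were chosen after seeing the data; the other alternatives were planned. For knockout against control, the count of genes in libraries labelled rostral (0) became 4 with DESeq2, 2 without a filter, 2 with all 12 libraries in a 4-group fit and 1 with limma-voom. The caudal count (8) became 71, 57, 3 and 4 in these fits, and 5 with X and Y genes left out, since 3 Rpl30-like copies lie on X. With Xist as a covariate the counts were 0 and 6. The summed count (6) became 33 with DESeq2, 110 without a filter and 13 without the 2 control libraries, where 2 of the 3 control sums hold caudal counts alone, so that this count decides nothing. Without a filter, the genes tested in the summed comparison went from 18937 to 36318 and edgeR's median prior degrees of freedom from 4.61 to infinity, which lowers every p of a given F. Caudal against rostral in knockout embryos went from 0 to 53 with DESeq2. The cause of the other shifts was not tested. With all 12 libraries as separate samples and 0, 1, 2, 3 and 4 surrogate variables, 4, 5, 7, 10 and 16 genes were called, of which 4, 4, 5, 6 and 4 were among the 6 of the summed comparison; 2 was chosen after these were seen.

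Leaving out 1 titled embryo gave 0 to 0 genes in rostral, 2 to 8 in caudal and 3 to 21 in summed comparisons, 0 to 3 for caudal against rostral in controls, and 0 to 0 in knockouts and for the interaction. Lists ranged from 2 to 9, 7 to 19, 10 to 15, 6 to 19, 4 to 12 and 4 to 16 in the same order. With an estimated correlation and with fry's directional test, 0 lists were called in all 6 comparisons, and with fry's test for either direction 7 in the summed, 5 in the caudal and 1 in the interaction one; without the 2 control libraries 14 were called in the rostral one, where 1 control library is then left, so that this count decides nothing either. Egfr in knockouts stayed at 16.9% to 23.9% of control in rostral and 16.4% to 19.5% in caudal libraries. Of the named genes, 2 changed sign, each without 1 embryo: Nr2f1 in controls (from -0.17 without embryo 9 to 2.52 without embryo 3) and Egfr in the interaction (from -0.51 without embryo 2 to 0.086 without embryo 7). For the 28 genes of the summed comparison, 379 of 419 values kept direction and side of the threshold, 7 lost the call and 33 gained one; for the 23 of the caudal one, 280 of 342 did, 38 lost it and 24 gained one.

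With the number before the embryo number as a replicate block, 0 genes were called in rostral, 6 in caudal and 8 in summed comparisons, and the caudal calls of Cdh13 (adjusted p = 0.051) and Gm7429 (adjusted p = 0.0969) were lost; with no replicate block for the embryo, 0 were called for caudal against rostral in either genotype and for the interaction. At the depth of these libraries, 0 counts of a gene allow up to 0.0987 to 0.119 CPM in 1 library.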

Other observations

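The fits of this part were chosen after the results were seen, and 2 surrogate variables were settled on after fits with 0 to 4 had called 4, 5, 7, 10 and 16 genes. In the fit of all 12 libraries as separate samples with 2 surrogate variables, the peptide transporter gene Slc15a2 (log2 fold change 0.86, SE 0.12, adjusted p = 0.0323 by edgeR) and Klf6 (-0.44, SE 0.06, adjusted p = 0.0361) were called beside Egfr, Gh, 2610507I01Rik, Hes5 and Olig2. This fit counts the 6 libraries of a genotype as replicates although they are titled as parts of 3 embryos, so its p-values rest on more replicates than there are embryos. The MAP kinase phosphatase genes Dusp5 (-0.93, SE 0.15) and Dusp10 (-0.65, SE 0.10), the latter named after its value was seen, each had an adjusted p of 0.0518. Over 15 alternatives to the embryo sums, the adjusted p ran from 2.44e-16 to 1 for Slc15a2 and from 9.4e-08 to 1 for Klf6, each called in 4, and from 9.4e-08 to 1 for Dusp5, called in 2. Olig1 was not called in that fit (adjusted p = 0.135), and its adjusted p ranged from 4.89e-39 to 0.135 over 15 alternatives. That of Hes5 was 0.00205 in that fit and 0.404 without surrogate variables, and ranged from 1.55e-43 to 0.404. Over the same 15 alternatives Gh, 2610507I01Rik and Olig2 were called in every one, with highest adjusted p of 0.00277, 0.0173 and 0.0498.

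Genes within 10 Mb of Egfr are given as values without an explanation. In the embryo sums, 2 of 85 such genes (2.35%) had an unadjusted p under 0.05, against 3.40% elsewhere (Fisher's exact test, two-sided p = 1). Of the 5 genes called beside Egfr in the sums, 2 (Gh and 2610507I01Rik) lie on chromosome 11. On chromosome 11 as a whole, 2.95% of 1390 genes had an unadjusted p under 0.05, against 3.43% on other chromosomes. The two-sided p of Fisher's exact test was 0.397.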
